A study of Mus musculus with 6 samples.

How the data were processed

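RNA was measured by sequencing in 6 libraries from the brain tissue that the labels call PFC, taken from mice aged 6 months. Per the labels, 2 libraries came from control mice of a C57BL/6 by C3H background, 2 from PS19 mice, which carry a human tau transgene with the P301S change, and 2 from PS19 mice given WDR5-0103, a small molecule that binds WDR5. Control and PS19 mice of the first 2 groups received vehicle, and the labels describe the libraries of each group as biological duplicates. The groups are called control, tau and treated tau here, and libraries are numbered as in the sample titles. The file headers give the same groups but other numbers for 4 libraries: 3 for control 2, tau 2 and treated tau 2, and 2 for tau 1.

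Per the labels' protocols, total RNA was depleted of ribosomal RNA, made into strand-specific libraries and sequenced on a HiSeq instrument, and reads were trimmed with Cutadapt and aligned with TopHat2 at its default parameters to mouse RefSeq mRNAs. The submitters' processing notes name TopHat2, SAMtools, featureCounts and edgeR and the genome build mm10; their versions, the strand setting of the counting and the treatment of reads with several alignments are not given in the sources used here. The deposited values are whole-number read counts per gene symbol, not normalized, with 1 table per library. The 4 control and tau tables list 54429 symbols and the 2 treated tau tables list 54134, of which 53640 are shared; 789 symbols appear only in the former and 494 only in the latter. Symbols outside the shared set held 0.346% of the counts of the library labelled control 1 and between 0.333% and 0.352% of the others, and stayed out of the tests. No table has a line for unassigned reads. Total counts ranged from 17690811 in tau 2 to 34774643 in treated tau 1; these counts carry no molecular identifiers, so the floor of 3 counts per library used for a gene with no counts covers counting error only.

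Counts of the shared symbols were filtered with filterByExpr (minimum count 10), scaled by TMM and fitted with the quasi-likelihood test of edgeR 4.0.16 (glmQLFit and glmQLFTest, two-sided, legacy option off) in R 4.3.3. One fit over all 6 libraries, with no covariate, left 3 residual degrees of freedom. Adjusted p means the Benjamini-Hochberg value over the 20694 genes tested, and a gene was called at an adjusted p under 0.05. CPM are TMM-scaled counts relative to library size, given as mean ± SD over the 2 libraries of a group, and log2 fold changes are given with their standard error (SE). Gene positions, classes, GC content and transcript lengths came from GENCODE M21, which is on the mm10 assembly; 20557 of the tested symbols matched. A gene's share of 50-mers found in another gene marked near-copies (above 5%, 3456 genes), and 12958 protein-coding genes at 1 locus below that limit are called single-copy coding genes. Only exact matches were counted, so a gene whose copies differ at scattered bases can fall below the limit.

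Gene lists fixed in advance were tested with camera of limma 3.58.1 on log2 CPM with a prior count of 2 and a preset correlation of 0.01, adjusted over the 29 lists of a comparison; camera with an estimated correlation and fry stand beside it. The 17 pathway lists were H3K4 methyltransferase complexes, H3K4 demethylases, ionotropic glutamate receptors, GABA signalling, presynaptic vesicle machinery, postsynaptic scaffold and plasticity, voltage-gated ion channels, immediate early genes, glucocorticoid-induced genes, disease-associated microglia genes, reactive astrocyte genes, complement, interferon-induced genes, chaperones and the unfolded protein response, nuclear-encoded oxidative phosphorylation, cytosolic ribosomal proteins, and Alzheimer disease risk and amyloid processing genes. The 12 cell type lists were excitatory cortical neurons, inhibitory interneurons, astrocytes, homeostatic microglia, oligodendrocytes, oligodendrocyte precursors, endothelial and mural cells, meninges and fibroblasts, choroid plexus, striatal projection neurons, olfactory bulb neurons and blood. Prnp, Mapt and sex-linked transcripts were read as label checks. Genes named per comparison are, of the called genes with average log2 CPM of at least 1 and no overlap between the groups' libraries, the 10 with the largest fold in each direction, or, where fewer were called, the 5 with the smallest p. They also include up to 4 called members of each list, or 2 members with the smallest p as values. Prnp, Mapt, Sgk1 and Wdr5 were always named. Predicted genes with no functional symbol were counted and passed over for the next. The tests, lists, this rule and most alternatives were chosen before the data were examined. The single-copy coding refit, the GC content and length offsets (mgcv 1.9.3), the sex term, the removal of X and Y genes, the joining of 79 renamed symbol pairs, the fit of the control and tau tables with all of their symbols and the removal of 2 libraries together were chosen after.

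Alternatives covered RLE and upper-quartile scaling, DESeq2 1.42.0, limma-voom, the edgeR exact test, the legacy quasi-likelihood fit, looser and stricter filters, fits of only the 4 libraries compared, the replicate number as a block, each library left out and thinned counts. Other thresholds were also tried (adjusted p under 0.1, a test against a fold of 1.2, and unadjusted p under 0.05 with a fold of 1.2). The comparisons against tau share its libraries, so 100 sets of unchanged groups were simulated and refitted, with each gene drawn independently of the others. The 2 libraries of a group differed well beyond counting noise, with a chi-square per degree of freedom of 15.3, 10.2 and 12.3 in control, tau and treated tau, so all 6 were kept as separate samples. The fit was tested on simulated counts with 200 changed genes. For tau against control (20099 genes) it recovered 37.3%, 79.1% and 92.4% of genes changed 1.5-fold, 2-fold and 4-fold, with 25 false calls among 164. For treated tau against tau (20104 genes) these shares were 35.8%, 88.1% and 100%, with 20 false calls among 169, and for treated tau against control (20099 genes) 41.8%, 71.6% and 98.5%, with 23 among 165. The share of false calls was thus above the nominal level in all 3 comparisons. In 20 simulated runs of tau against control (20694 genes) the ion channel list, shifted by 0.5 in log2, was called 20 times with the preset correlation and 4 times with an estimated one. The simulated genes varied independently, which favours the preset. In the data the estimated correlation was 0.34 for that list and up to 0.97 (oligodendrocytes), so these runs do not decide between the 2 settings. The edgeR results of the authors were not used here.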

Results

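The series measured RNA in PFC tissue of control mice, of PS19 mice carrying P301S tau, and of PS19 mice treated with WDR5-0103, with 2 libraries in each of the 3 groups. WDR5 is a shared subunit of the complexes that methylate histone H3 at lysine K4, and the series title names this mark as the target. Gene counts summed to 24525020 and 25264641 in the libraries labelled control 1 and control 2. They summed to 25685236 and 17690811 in tau 1 and tau 2, and to 34774643 and 27772812 in treated tau 1 and treated tau 2. In a principal component analysis of log2 CPM, the first component held 45.8% of the variance and set the treated tau libraries (56.6 and 63.4) apart from the other 4, which lay between -34.6 and -24.4.

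Prnp, the gene whose promoter cassette drives the PS19 transgene, served as a check of the labels. It stood at 1654 CPM in the library labelled control 1 and at 876 CPM in control 2, while the tau libraries had 1684 and 1472 CPM and the treated tau libraries 1876 and 1594 CPM. The library labelled control 1 therefore lay at the level of the transgenic libraries, against its label and against its file header, which also names a control, and every direction drawn from the control group below includes it. Prnp shares 6.15% of its 50-mers with another gene, just above the near-copy limit. Mapt, the mouse tau gene, had 576 and 450.4 CPM in the libraries labelled control 1 and control 2, 574 and 589.7 in tau, and 459 and 497 in treated tau. Prnp did not pass in any comparison over the 6 libraries (adjusted p = 0.638 for tau against control and 0.368 for treated tau against control), and without the library labelled control 1 it passed in treated tau against control (log2 fold change 0.99, adjusted p = 0.000951). Its log2 fold change for tau against control was 0.32 over all libraries and -0.07 without control 2.

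Sex-linked transcripts differed between libraries of the same group and between groups. Xist, the RNA that silences an X chromosome in female cells, was at 318 CPM in control 2 and at 186 and 235 CPM in the tau libraries, against 0.197 CPM in the library labelled control 1 and 2.43 and 1.75 CPM in the treated tau libraries. The Y-linked helicase gene Ddx3y showed the reverse, with 95.2 CPM in the library labelled control 1, 108 and 91.2 CPM in treated tau, and 0.314, 0.391 and 0.115 CPM in the other libraries. By these transcripts both tau libraries came from females and both treated tau libraries from males, so sex and treatment cannot be told apart in that comparison.

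**Figure D1:**
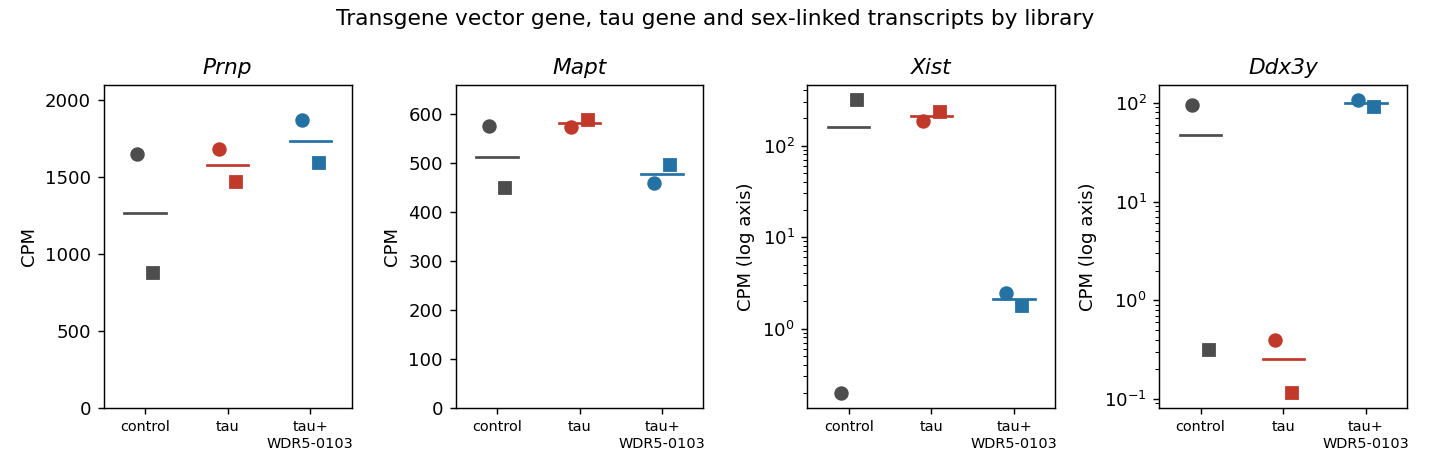
CPM of Prnp, Mapt, Xist and Ddx3y (the last 2 on log axes) in each library, with circles for replicate 1, squares for replicate 2 and a line at the group mean. Prnp in the library labelled control 1 (1654 CPM) lies among the tau and treated tau libraries, and Xist and Ddx3y part the libraries by sex.

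Tau was compared with control to ask what the P301S tau transgene changes in this tissue. The genes with the smallest p-values were lower in tau and included neuronal genes. Shank1, a scaffold of excitatory synapses (chromosome 7, 44310253 to 44360572), had 149 ± 0.344 CPM in control and 89.9 ± 7.02 CPM in tau (SD, n = 2 libraries each), a log2 fold change of -0.73 ± 0.09 (SE). Scube1, a secreted EGF-repeat protein, had a log2 fold change of -0.77 ± 0.10, Ndnf, a secreted neurotrophic factor, -0.90 ± 0.12, Dcx, a microtubule-binding protein of young neurons, -0.93 ± 0.15, and Snhg11, a host transcript of a small nucleolar RNA, -0.46 ± 0.07. The 5 genes of smallest p in the other direction were Enpp2, which makes lysophosphatidic acid (0.41), Selenop, a selenium carrier (0.45), the G protein subunit gene Gng3 (0.46), the calmodulin gene Calm2 (0.32) and the metallothionein gene Mt1 (0.53).

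None of these genes passed the threshold in the edgeR quasi-likelihood test over the 6 libraries. All of them passed with DESeq2, and all but Gng3 and Calm2 with the edgeR exact test. The quasi-likelihood test of edgeR called 0 of 20694 genes, with 2059 at an unadjusted p under 0.05 (892 higher and 1167 lower, where 1034.7 would be reached with no effect). The smallest adjusted p was 0.161, shared by Scube1, Shank1 and Ndnf. DESeq2 called 55 genes (22 higher, 33 lower) of the 7053 to which it gave an adjusted p. Over all 20694 genes the edgeR exact test called 49 (8 higher, 41 lower), and limma-voom and the legacy quasi-likelihood fit 0 each. Without control 2 the count was 98 genes (11 higher, 87 lower) and Shank1, Scube1, Ndnf, Snhg11 and Dcx passed (adjusted p from 0.0208 to 0.0383). Without tau 2 it was 9, while leaving out both the library labelled control 1 and tau 2 gave 130. Sgk1, a kinase gene induced by glucocorticoids, had 207 CPM in tau 2 against 75.2 in tau 1, 67.3 in the library labelled control 1 and 64.7 in control 2 (adjusted p = 0.452). Wdr5 had 27.0 ± 1.01 CPM in control and 30.5 ± 1.09 CPM in tau (adjusted p = 0.57). Mapt had a log2 fold change of 0.18 ± 0.11 (adjusted p = 0.577).

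As groups, 3 lists of neuronal excitability and synapse genes fell in tau against control by camera with the preset correlation. Of 22 voltage-gated ion channel genes, 17 had negative fold changes (median -0.16), with Cacna1g, a T-type calcium channel (-0.47), and Cacna1a, the P/Q-type channel of presynaptic terminals (-0.47), leading. Of 20 postsynaptic scaffold genes 16 were negative (median -0.14), led by Shank1 and by Nlgn2, an adhesion molecule of inhibitory synapses (-0.58). Of 15 ionotropic glutamate receptor genes 12 were negative (median -0.12), led by the kainate receptor gene Grik5 (-0.45) and the NMDA receptor gene Grin2b (-0.35). The camera adjusted p was 0.0295 for each of the 3 lists, and 0.626 with an estimated correlation (adjusted p). As deviations from the mean of all libraries, the ion channel medians were -0.087 in the library labelled control 1, 0.098 in control 2, and -0.175 and -0.070 in tau. The library labelled control 1 thus lay below tau 2. In the same order the postsynaptic medians were -0.061, 0.147, -0.068 and -0.121, and the glutamate receptor medians 0.027, 0.0995, -0.066 and -0.097. No member passed over all genes; adjusted over the list alone, 4 ion channel genes, 3 postsynaptic genes and 1 glutamate receptor gene passed, all lower. All 3 calls were lost without control 2, without tau 1 and with either treated tau library left out, and those of the postsynaptic and glutamate receptor lists also without tau 2. With GC content and length offsets all 3 calls were lost as well (adjusted p from 0.37 to 0.374), as they were with no filter on low counts (0.0912).

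The 6 lists that rose in tau against control were partly cell type markers. All 12 markers of striatal projection neurons were positive (median 0.82), among them Rgs9, a regulator of G protein signalling (1.19), and so were all 12 oligodendrocyte markers (median 0.85), among them the myelin genes Mal (1.05) and Cldn11 (0.88). Of 15 glucocorticoid-induced genes 14 were positive (median 0.48), with Mt1 and the leucine zipper gene Tsc22d3 (0.76) leading. Chaperone genes (15 of 15 positive, median 0.23, led by Hsp90aa1 at 0.24 and Herpud1 at 0.26) rose as a list too. So did oxidative phosphorylation genes (17 of 17, median 0.14, led by Sdha at 0.17 and Uqcrc2 at 0.19). Ribosomal protein genes (19 of 22, median 0.13, led by Rpl4 at 0.20 and Rps3 at 0.20) completed the set. Camera adjusted p was 1.81e-06 for the striatal, 1.23e-05 for the glucocorticoid, 0.000783 for the oligodendrocyte, 0.00208 for the oxidative phosphorylation, 0.0112 for the chaperone and 0.0432 for the ribosomal list, and for all 6 adjusted p = 0.626 with an estimated correlation. No member was called over all genes; adjusted over the list alone, 10 striatal and 9 glucocorticoid-induced genes passed. The list medians of tau 2 stood apart from the mean of all libraries, at 1.09 for striatal, 0.96 for oligodendrocyte and 0.52 for glucocorticoid-induced genes, against 0.15, -0.16 and -0.05 in tau 1, and control 2 had -0.88 for oligodendrocytes. Without tau 2, 4 lists were called in place of 9, and the oligodendrocyte, chaperone and ribosomal calls were lost. The oligodendrocyte, oxidative phosphorylation and ribosomal calls were lost without control 2, the latter 2 also without tau 1, and the chaperone call without the library labelled control 1. The oxidative phosphorylation (0.0585) and ribosomal (0.37) calls were lost with GC content and length offsets, and the latter also with no filter (0.0529).

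The other 20 lists did not pass in tau against control. The 4 tested markers of olfactory bulb neurons had a median of -3.19 (adjusted p = 0.102; 4 lower adjusted over the list alone). The library labelled control 1 stood at 3.48 in log2 above the mean of the libraries and no other library exceeded -0.47. Cdhr1, a cadherin of mitral cells, led (-3.13). Interferon-induced genes had a median of -0.40 (adjusted p = 0.0586; Mx1, an antiviral GTPase, -1.74), complement genes 0.17 (adjusted p = 0.0964; C1qb 0.39), homeostatic microglia 0.19 (adjusted p = 0.1) and disease-associated microglia genes 0.12 (adjusted p = 0.219; Ctsb 0.20). The adjusted p was 0.126 for choroid plexus, 0.29 for blood, 0.301 for endothelial and mural cells, 0.304 for Alzheimer disease risk genes, and 0.397 for each of GABA signalling, H3K4 methyltransferase complexes and inhibitory interneurons. It was 0.481 for meninges, 0.521 for presynaptic machinery, 0.634 for reactive astrocyte genes, 0.638 for H3K4 demethylases, 0.649 for astrocytes, 0.711 for immediate early genes and for oligodendrocyte precursors, and 0.97 for excitatory cortical neurons. Adjusted over the list alone, 2 presynaptic genes and 2 H3K4 methyltransferase genes, 1 endothelial gene and 1 astrocyte gene were lower, and 1 GABA signalling gene, 1 astrocyte gene and 1 choroid plexus gene were higher. The oligodendrocyte precursor list had a positive median (0.12) and a negative mean (-0.02).

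**Figure D2:**
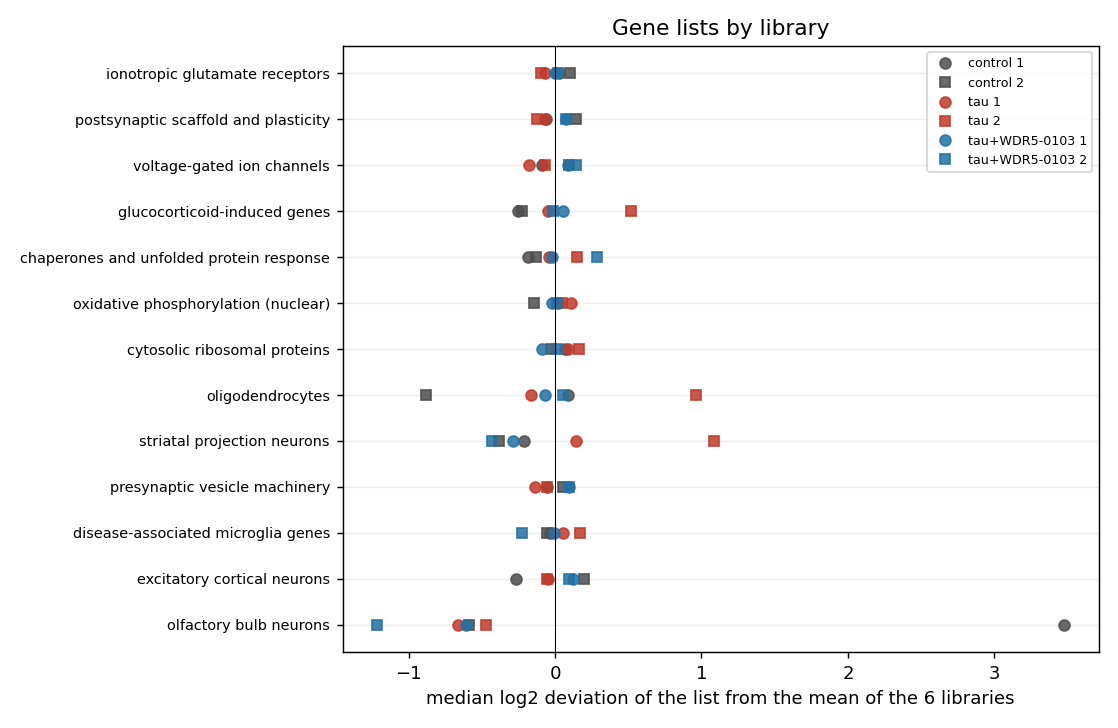
Median log2 deviation of gene lists (vertical axis) from the mean of the 6 libraries, 1 point per library, circles for replicate 1 and squares for replicate 2, in grey for control, red for tau and blue for treated tau. The olfactory bulb list lies at 3.48 in the library labelled control 1, and the striatal and oligodendrocyte lists at 1.09 and 0.96 in tau 2.

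Treated tau was compared with tau to ask what the WDR5 inhibitor changes in tau transgenic tissue. Bsn, a scaffold of the presynaptic active zone (chromosome 9, 108096022 to 108190384), went from 452 ± 49.5 to 670.4 ± 17.6 CPM (SD, n = 2 libraries each), a log2 fold change of 0.57 ± 0.11 (SE). Kmt2d, a histone H3K4 methyltransferase (chromosome 15, 98831669 to 98871204), went from 77.3 ± 7.25 to 120.4 ± 10.8 CPM (0.64 ± 0.12). Nlgn2 rose by 0.52 ± 0.12 and Shank1 by 0.48 ± 0.09, as did Egr3, a transcription factor induced by neuronal activity (0.70 ± 0.15), and Cldn5, a tight junction protein of brain endothelium (0.88 ± 0.19). Adjusted p in edgeR was 0.0174 for Bsn, 0.0178 for Kmt2d, 0.0414 for Nlgn2, 0.0199 for Shank1, 0.0276 for Egr3 and 0.0286 for Cldn5. Striatal markers fell, with Drd2, a dopamine receptor gene, at -1.84 ± 0.39, the orphan receptor gene Gpr6 at -2.20 ± 0.47 and Rgs9 at -1.18 ± 0.27 (adjusted p = 0.0308, 0.0315 and 0.0469).

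None of these single-copy coding genes passed when the 12958 single-copy coding genes were fitted alone, where the adjusted p was 0.334 for Bsn, Kmt2d and Shank1, 0.392 for Nlgn2, 0.371 for Egr3, 0.38 for Cldn5, Drd2 and Gpr6 and 0.435 for Rgs9. Without treated tau 2 the adjusted p of Bsn, Kmt2d, Nlgn2, Shank1, Egr3, Cldn5, Drd2, Gpr6 and Rgs9 ranged from 0.0611 to 0.329, and all 9 calls were lost. Without treated tau 1 all but that of Shank1 (0.039) were lost (0.0523 to 0.283), without tau 1 those of Bsn, Kmt2d, Nlgn2, Shank1, Egr3 and Cldn5 (0.1 to 0.312), and without tau 2 those of Nlgn2, Cldn5, Drd2, Gpr6 and Rgs9 (0.0982 to 0.258). In the fit of all genes, Shank1 and Nlgn2 also lost their calls with GC content and length offsets, and Nlgn2, Drd2 and Rgs9 with a stricter filter on low counts. With no filter Nlgn2, Egr3, Cldn5, Drd2, Gpr6 and Rgs9 lost theirs, with limma-voom Drd2 and Rgs9, with the legacy fit Rgs9, and with thinned counts Gpr6.

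**Figure D3:**
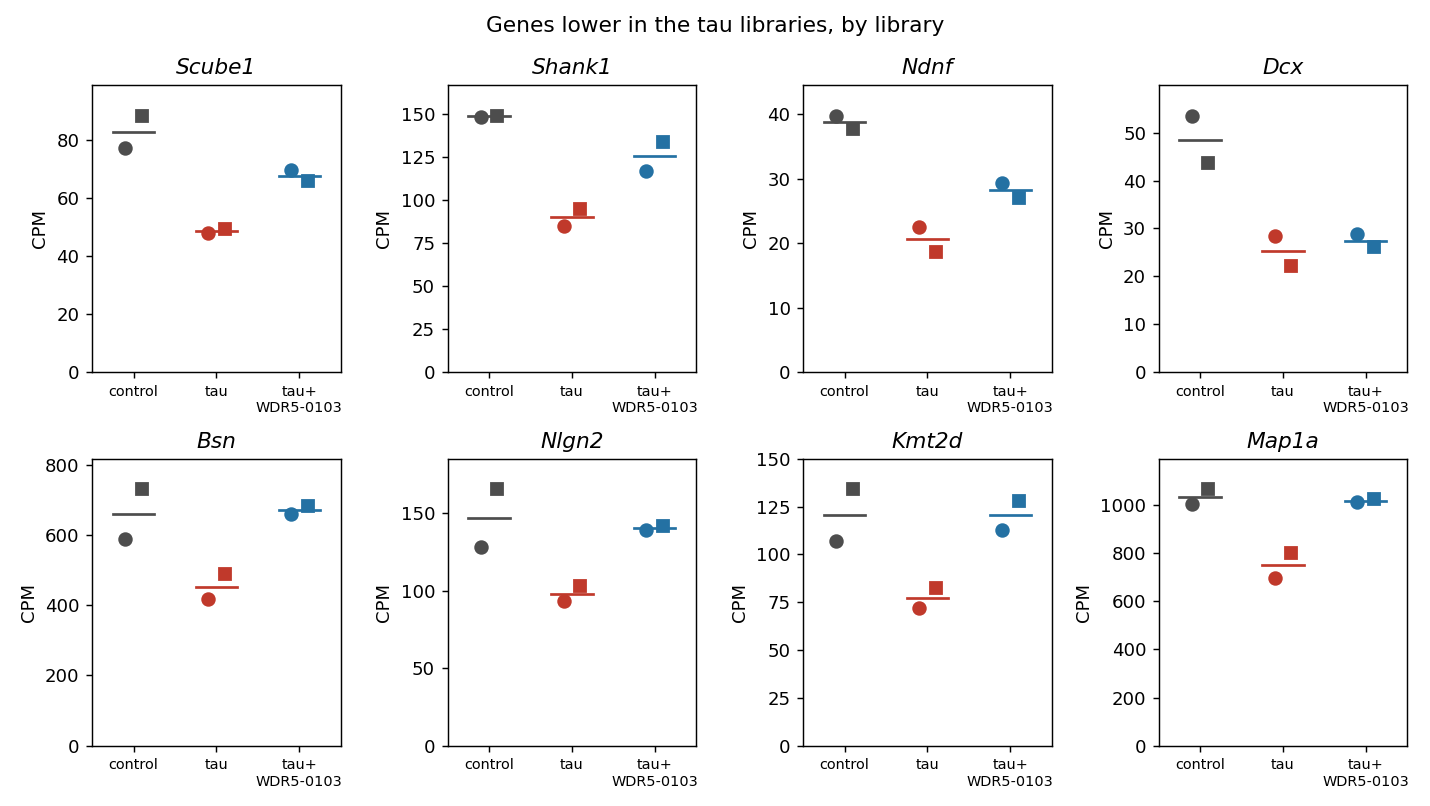
CPM of 8 genes in each library, circles for replicate 1, squares for replicate 2 and a line at the group mean. In each panel both tau libraries lie below both control libraries, the library labelled control 1 included. The genes were picked as lower in tau, so this order restates the choice. None was called in tau against control by the edgeR quasi-likelihood test. Bsn has 659 ± 98.8, 452 ± 49.5 and 670.4 ± 17.6 CPM (mean ± SD) in control, tau and treated tau.

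By class, most genes that differed between treated tau and tau were pseudogenes and genes with near-copies. The edgeR test called 779 genes, 639 higher and 140 lower. Of the 779, 579 (74.3%) were pseudogenes, of which 551 were higher, while pseudogenes made up 9.26% of the genes tested, and 71.7% of the called genes shared over 5% of their 50-mers with another gene, against 14.7% of the genes not called. The largest rises that the naming rule gave were Uty and Ddx3y, both on the Y chromosome, and Aldoart2, a testis aldolase gene (0.42 ± 0.513 to 45.0 ± 0.2 CPM; chromosome 12, 55565239 to 55566896). Next came the myosin light chain gene Myl12b (3.53 ± 0.11), Jakmip1 (3.28 ± 0.10), Csl (3.23 ± 0.21), the Elongator subunit gene Elp6 (9.55 ± 2.97 to 55.2 ± 5.28 CPM), Rpl32l (2.11 ± 0.19), Ubxn6 (1.96 ± 0.12) and Rpl38 (1.75 ± 0.28). Bc1, a brain RNA that represses translation at synapses (chromosome 7, 144914470 to 144914637), fell (-5.27 ± 0.22 in log2), from 4769 and 5342 CPM in tau to 116 and 146 CPM in treated tau. It shares 31.1% of its 50-mers with other genes. The further falls by the rule were Capn11 (-4.18), the ribosomal protein genes Rps28 (-3.07) and Rpl35 (-2.85), the signal recognition particle RNAs Rn7s6 (-2.64) and Rn7s2 (-2.40), the tubulin gene Tuba1c (-2.55), Mir6236 (-2.52) and Drd2. The 5.8S ribosomal RNA gene n-R5-8s1 had 0 counts in both treated tau libraries and 49.6 ± 12.3 CPM in tau, at least 497-fold lower at a floor of 3 counts per library.

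Adjusted p was between 2.24e-07 (Jakmip1) and 0.0498 (Ddx3y) for the rises and between 1.5e-06 (Bc1) and 0.0308 (Drd2) for the falls. Near-copies can exchange reads, so the values of Myl12b, Jakmip1, Csl, Elp6, Rpl32l, Rpl38, Bc1, Rps28, Rpl35, Rn7s6, Rn7s2 and Tuba1c are uncertain, and all genes called here were counted on a different symbol list in the treated tau tables than in the others. Calls were lost for Uty and Ddx3y when each of the 4 libraries compared was left out in turn (adjusted p from 0.322 to 0.379 without tau 1, 0.222 to 0.246 without tau 2, 0.111 to 0.172 without treated tau 1 and 0.13 to 0.157 without treated tau 2). The call of n-R5-8s1 was lost without either treated tau library (0.123 and 0.102). Those of Rpl38 and Tuba1c were lost without treated tau 1 (0.058 and 0.0744), that of Tuba1c also without tau 1 (0.0751), and that of Mir6236 without tau 2 and without treated tau 2 (0.069 and 0.092). Uty, Ddx3y and n-R5-8s1 also lost their calls with no filter and with limma-voom, Uty and Ddx3y with a stricter filter and with the legacy fit, and Ddx3y with GC content and length offsets. When the single-copy coding genes were fitted alone, Uty, Ddx3y and Capn11 lost theirs.

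**Figure D4:**
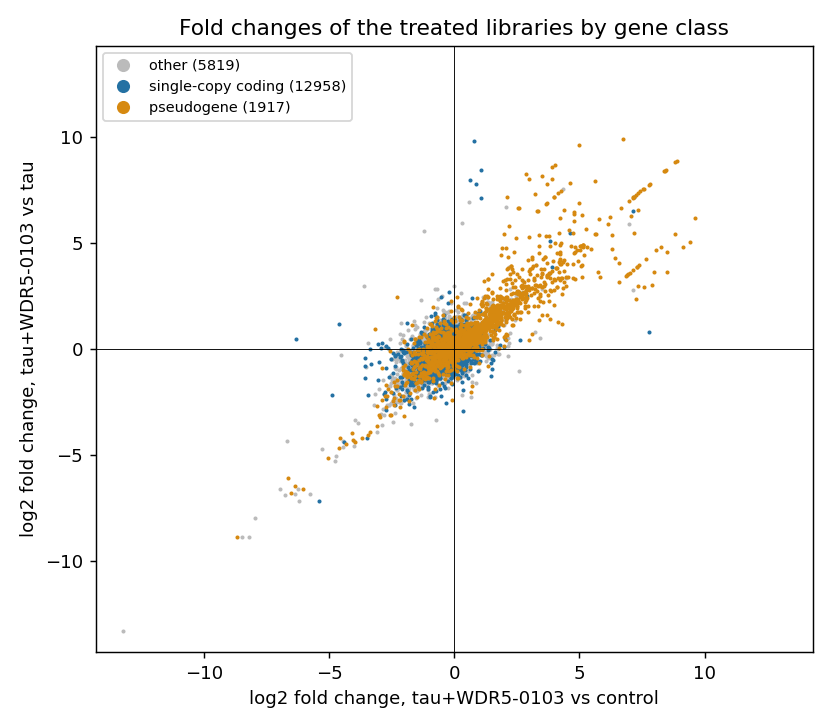
Log2 fold change of each tested gene in treated tau against control (horizontal axis) and against tau (vertical axis), with 1917 pseudogenes in orange, 12958 single-copy coding genes in blue and the other genes in grey. Pseudogenes make up most of the points far from 0 in the upper right, and both axes share the treated tau libraries.

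Among single-copy coding genes, 67 were called in the test over all genes (47 higher, 20 lower). When these genes were fitted alone, 5 of 12958 passed, all higher. Among them were Ubxn6 (16.9 ± 1.19 to 66.1 ± 0.459 CPM; chromosome 17, 56067045 to 56075028), Aldoart2, and the predicted genes BC048507 and Gm4707, the latter 2 chosen after their values were seen. The near-copy limit counts exact matches only, so reads shared with less similar copies are not excluded for these genes. In the all-gene test the cytoskeletal genes Plec (0.52 ± 0.09) and Map1a (0.44 ± 0.08), the cadherin gene Celsr2 (0.59 ± 0.11) and the transcription factor gene Srf (0.71 ± 0.13) rose. Sod1, a superoxide dismutase (-0.57 ± 0.09), the ATP synthase gene Atp5k (-0.54 ± 0.09) and Rps24 (-0.50 ± 0.08) fell. These 7 genes were also chosen after their values were seen, and had adjusted p from 0.112 (Sod1) to 0.334 (Srf and Celsr2) when fitted alone. With a sex term made from Xist and the Y-linked transcripts, 166 genes were called in place of 779 (102 higher and 64 lower, in place of 639 and 140), 108 of them among the 779. The sex effect in that fit rests on the library labelled control 1 and control 2 alone, since the other groups hold 1 sex each. The lower count therefore does not show that the calls lost were due to sex. With the same term 762 genes were called in treated tau against control, in place of 873. A stricter filter on low counts gave 465 genes. The count was 355 without tau 1, 504 without tau 2, 429 without treated tau 1 and 423 without treated tau 2. The 7 genes lost their calls without 1 or more of these libraries. Without treated tau 2 all 7 did (0.0501 to 0.151), and without treated tau 1 Plec, Map1a, Celsr2, Sod1 and Rps24 (0.0567 to 0.106). Without tau 1 all but Rps24 did (0.0591 to 0.16) and without tau 2 Plec, Srf, Atp5k and Rps24 (0.0502 to 0.0926).

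As groups, voltage-gated ion channel, postsynaptic and presynaptic genes rose in treated tau against tau. Of 22 ion channel genes 20 were positive (median 0.22; 0 called over all genes by edgeR and 7 adjusted over the list alone), led by Cacna1a (0.41) and the potassium channel gene Kcnc1 (0.45). These 2 genes passed over all genes without the library labelled control 1 (0.0193 to 0.05) and without control 2 (0.0192 to 0.0491), Kcnc1 also without tau 2 (0.0254), both with DESeq2 and with the exact test, and Cacna1a with only the 4 libraries compared. Of 20 postsynaptic genes 18 were positive (median 0.14; Shank1 and Nlgn2 called, 5 adjusted over the list alone), and of 18 presynaptic genes 15 (median 0.14; Bsn called, 3 adjusted over the list alone). Striatal markers fell, 12 of 12 negative (median -0.90; 3 called, 9 adjusted over the list alone), and so did disease-associated microglia genes, 16 of 16 negative (median -0.17; none called), with Lgals3 (-1.82, near the detection floor) and Csf1 (-0.29) having the smallest p. Camera adjusted p was 2.11e-05 (striatal), 0.000315 (ion channels), 0.0105 (postsynaptic and microglia lists) and 0.0398 (presynaptic), and for all 5 adjusted p = 0.908 with an estimated correlation. Of the cell type lists that did not pass, 12 of 12 oligodendrocyte markers were negative (median -0.50, adjusted p = 0.142), 9 of 11 homeostatic microglia markers were negative (median -0.13, adjusted p = 0.382) and 11 of 11 excitatory cortical neuron markers were positive (median 0.13, adjusted p = 0.184). The list changes are therefore not separated from a difference in tissue composition, with tau 2 at 0.96 for oligodendrocyte and 1.09 for striatal markers. Without tau 2, 2 lists were called in place of 5, and the presynaptic, postsynaptic and microglia calls were lost. The presynaptic call was also lost without tau 1 and without either treated tau library, the postsynaptic call without tau 1, and the microglia call without treated tau 2.

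The other lists did not pass in treated tau against tau, although some had called members. Ribosomal protein genes had 8 members lower and none higher (5 higher and 9 lower adjusted over the list alone; camera adjusted p = 0.0521). Among them were Rpl32 (-0.92 ± 0.09), Rps14 (-0.69 ± 0.08) and Rpl4 (-0.44 ± 0.07), and 17 of the 22 members have near-copies. Of the oxidative phosphorylation genes Cox6c (-0.72 ± 0.09, adjusted p = 0.00177) and Atp5o (-0.43 ± 0.08, adjusted p = 0.0179) fell (camera adjusted p = 0.0552). Kmt2d was the single called member of the H3K4 methyltransferase list (camera adjusted p = 0.184), and Wdr5 itself had 30.5 ± 1.09 and 31.5 ± 1.29 CPM in tau and treated tau (adjusted p = 0.942). Camera adjusted p for the remaining lists lay between 0.126 (glucocorticoid-induced genes) and 0.905 (inhibitory interneurons); Egr3 was the 1 called immediate early gene and Cldn5 the 1 called endothelial gene. The Alzheimer disease risk, interferon, interneuron and choroid plexus lists had medians and means of opposite sign; the test pointed up for the first and down for the other 3. Sgk1 (log2 fold change -0.58, adjusted p = 0.673) turned to 0.32 without tau 2. Mapt had a negative fold change (-0.28 ± 0.11, adjusted p = 0.296) and passed as lower in treated tau without the library labelled control 1 (-0.28, adjusted p = 0.0455) and without control 2 (-0.28, adjusted p = 0.0486), as it did with only the 4 libraries compared. The calls of Atp5o and Rpl4 were lost without treated tau 1 (0.116 to 0.173), treated tau 2 (0.0825 to 0.146) and tau 1 (0.111 to 0.161), and that of Atp5o also without tau 2 (0.0881) and with no filter. Cox6c lost its call when the single-copy coding genes were fitted alone.

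Treated tau was compared with control to ask which differences from control remain under treatment. Dcx, which also had the lower value in tau, had a log2 fold change of -0.82 ± 0.14 (SE; 48.6 ± 7.05 to 27.4 ± 1.91 CPM, SD, n = 2 libraries each), a fall. The laminin gene Lama3 (-0.84 ± 0.13), the caspase gene Casp9 (-0.88 ± 0.15), Sod1 (-0.51 ± 0.09) and Cox6c (-0.56 ± 0.09) fell as well. Hspa1b, a stress-induced HSP70 chaperone, rose (1.14 ± 0.24), as did Egr3 (0.63 ± 0.14). Cd2ap, an adaptor gene linked to Alzheimer disease risk, fell (-0.60 ± 0.13). The secreted synaptic protein genes Cbln2 (0.48 ± 0.11) and Olfm3 (0.47 ± 0.10), the glycosyltransferase gene Galnt9 (0.63 ± 0.14), the histone chaperone gene Nap1l2 (0.42 ± 0.09) and the syntrophin gene Sntb2 (0.50 ± 0.11) rose. Dcx, Lama3, Casp9, Sod1, Cbln2, Olfm3, Galnt9, Nap1l2 and Sntb2 were chosen after their values were seen in this comparison. Adjusted p in edgeR was 0.00488 for Lama3, 0.00869 for Dcx, 0.0255 for Hspa1b, 0.033 for Cd2ap and 0.0406 for Egr3, and from 0.00642 (Cox6c) to 0.0361 (Cbln2) for the others. The control means include the library labelled control 1, and Shank1 (-0.25, adjusted p = 0.219), Sgk1 (0.51, adjusted p = 0.587), Mapt (-0.10, adjusted p = 0.7) and Wdr5 (0.22, adjusted p = 0.324) did not pass.

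By class the picture resembled that against tau. The edgeR test called 873 genes, 687 higher and 186 lower, of which 641 (73.4%) were pseudogenes, and 56 single-copy coding genes (18 higher, 38 lower). Aldoart2 (7.14 ± 0.33), Myl12b (3.81 ± 0.11), Jakmip1 (3.18 ± 0.10), Csl (2.76 ± 0.19), Elp6 (2.48 ± 0.17), Rpl3 (2.45 ± 0.43), Rpl32l (2.11 ± 0.18), Ubxn6 (2.11 ± 0.12), D9Wsu149 (1.73 ± 0.31) and Rpl38 (1.66 ± 0.27) had the largest rises by the rule. Bc1 (-4.77), Capn11 (-3.49), Rps28 (-2.92), Rpl35 (-2.83), Rn7s6 (-2.61), Rn7s2 (-2.44), Mir6236 (-2.34), the reductase gene Ndor1 (-1.82) and Tex47 (-1.66) had the largest falls, beside n-R5-8s1, at least 465-fold lower at the same floor. Rpl3, D9Wsu149, Ndor1 and Hspa1b have near-copies too, so their values are uncertain. Of the genes called against control, 641 were also called against tau, all in the same direction and 534 of them pseudogenes. Independent lists of these sizes would share 21.2 higher and 1.26 lower genes, and unchanged groups that share the treated libraries shared 0.76 on average in simulation. Those simulated groups had a mean of only 3.29 genes called against tau and 3.83 against control. Neither reference gives the overlap to expect once the treated tau libraries differ. Genes set apart in these shared libraries tend to be called in both comparisons and in the same direction. The log2 fold changes of the 2 comparisons correlated at 0.81 across 14522 genes, which are not independent replicates (simulated 0.49; covariance 0.208, simulated 0.0248), and part of that may come from the shared libraries.

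Fitted alone, 5 single-copy coding genes passed against control, the same 5 as against tau, Ubxn6, Aldoart2, BC048507 and Gm4707 among them. Called over all genes, Lama3, Dcx, Casp9, Sod1, Cox6c, Egr3, Cd2ap, Cbln2, Olfm3, Galnt9, Nap1l2 and Sntb2 lost their calls in that fit. So did Capn11 and Tex47. A stricter filter gave 514 genes. The count was 507 without treated tau 1 and 494 without treated tau 2. The calls of Dcx, Sod1, Olfm3, Nap1l2, Sntb2, Egr3 and Tex47 were lost without the library labelled control 1 (0.0504 to 0.183), without treated tau 1 (0.0593 to 0.234) and without treated tau 2 (0.0881 to 0.284). Those of Nap1l2, Sntb2, Cbln2, Galnt9, Egr3, Rpl3, D9Wsu149 and Mir6236 were lost without control 2 (0.0519 to 0.108), and those of Cbln2, Galnt9, Cd2ap and Hspa1b without the library labelled control 1 (0.0962 to 0.168) and without treated tau 2 (0.177 to 0.301). Further losses were Cd2ap without tau 1 (0.0585) and without tau 2 (0.0535), Lama3, Casp9, Rpl3 and Mir6236 without treated tau 2 (0.0615 to 0.122), and Rpl38 and Rps14 without treated tau 1 (0.0571 to 0.074). Cox6c, Capn11, D9Wsu149 and n-R5-8s1 lost their calls without treated tau 1 (0.053 to 0.112) and without treated tau 2 (0.0537 to 0.0975). With no filter n-R5-8s1, Mir6236, Tex47, Sntb2, Cbln2, Galnt9, Egr3 and Cd2ap lost their calls, with a stricter filter Sntb2, Cbln2, Galnt9 and Egr3, and with GC content and length offsets Tex47 and Cd2ap. Further losses were Egr3 with the legacy fit, Egr3 and Cbln2 with thinned counts, Cbln2 with upper-quartile scaling, Mir6236 with DESeq2, n-R5-8s1 with limma-voom and Cd2ap with only the 4 libraries compared.

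Chaperone and unfolded protein response genes were the 1 list that rose in treated tau against control, with 14 of 15 members positive (median 0.29; Hspa1b called, also adjusted over the list alone). Its camera adjusted p was 0.0119, and adjusted p = 0.851 with an estimated correlation, and the call was lost without treated tau 2. Ribosomal protein genes had 3 members higher and 5 lower (camera adjusted p = 0.443), with Rpl32 (-0.78 ± 0.09) and Rps14 (-0.53 ± 0.08) lower and Rpl3 higher. All 18 presynaptic genes were positive (median 0.09, adjusted p = 0.272), and 15 of 16 interferon-induced genes were negative (median -0.29, adjusted p = 0.093). Of the glucocorticoid-induced genes 12 of 15 were positive (median 0.31, adjusted p = 0.093), and the ion channel and postsynaptic lists had medians of 0.07 and 0.02 (adjusted p = 0.339 and 0.644). Striatal markers had a median of -0.01, with camera pointing down and fry up. The astrocyte and homeostatic microglia lists had medians above and means below 0, and the test pointed up for both. The number of lists called was 7 without control 2, 3 without tau 1 or without tau 2, and 2 without the library labelled control 1 or without treated tau 1.

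The last comparison asked whether genes that differ in tau move back under treatment. No gene was called in tau against control, so the number called there and called in the opposite direction in treated tau against tau was 0 with edgeR, limma-voom and the legacy fit. Simulations of unchanged groups that share the tau libraries gave a mean of 0.67 with the edgeR quasi-likelihood fit. The number was 21 with DESeq2 and 15 with the edgeR exact test, for which no unchanged groups were simulated. At an unadjusted p under 0.05 with a fold of at least 1.2 in both, 330 genes moved in opposite directions, against a simulated mean of 212 (174 to 248 in 100 simulations). Among single-copy coding genes 230 were lower in tau than in control and higher in treated tau than in tau at an unadjusted p under 0.05 in both, Shank1, Bsn, Nlgn2, Kmt2d and Map1a and the Y-linked Ddx3y, Eif2s3y, Kdm5d and Uty included, against a simulated mean of 70.7 and a highest value of 88. The reverse pattern held 109 genes, against 68.2 and 91. Across 11135 single-copy coding genes, which are not independent replicates, the log2 fold changes of the 2 comparisons correlated at -0.57 (simulated -0.51), with a covariance of -0.0469 (simulated -0.0217). Across all 14522 genes the correlation was -0.27, weaker than the simulated -0.51, with a covariance of -0.0415 (simulated -0.0263). The simulated genes varied independently and carried no GC content or tissue trend, so the simulated ranges may be too narrow. For tau against control alone, the simulations gave a mean of 979 genes at an unadjusted p under 0.05 (922 to 1053), against 2059 observed. The simulated groups shared the tau libraries as the data do. The 2 tau libraries could not be split into sets with a replicate each, and part of the excess may come from variation common to many genes in these libraries.

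These 230 genes had a median log2 fold change of -0.33 in tau against control, 0.33 in treated tau against tau and -0.0022 in treated tau against control. They were richer in GC (median 57.4%) than single-copy coding genes at large and had longer transcripts (5744 against 3565 bases). With GC content and length offsets their median was -0.22 in tau against control, with 229 of the 230 still negative, and 0.27 in treated tau against tau, and 98 of the 230 kept an unadjusted p under 0.05 in both comparisons. Genes picked on these folds in the same libraries keep their sign on average under any cause. Across 9209 expressed single-copy coding genes the fold change of tau against control correlated with GC content at a Spearman rho of -0.28 and that of treated tau against tau at 0.26. Without control 2 the number of called genes moving back was 14, without tau 2 it was 9, and without both the library labelled control 1 and tau 2 it was 90.

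**Figure D5:**
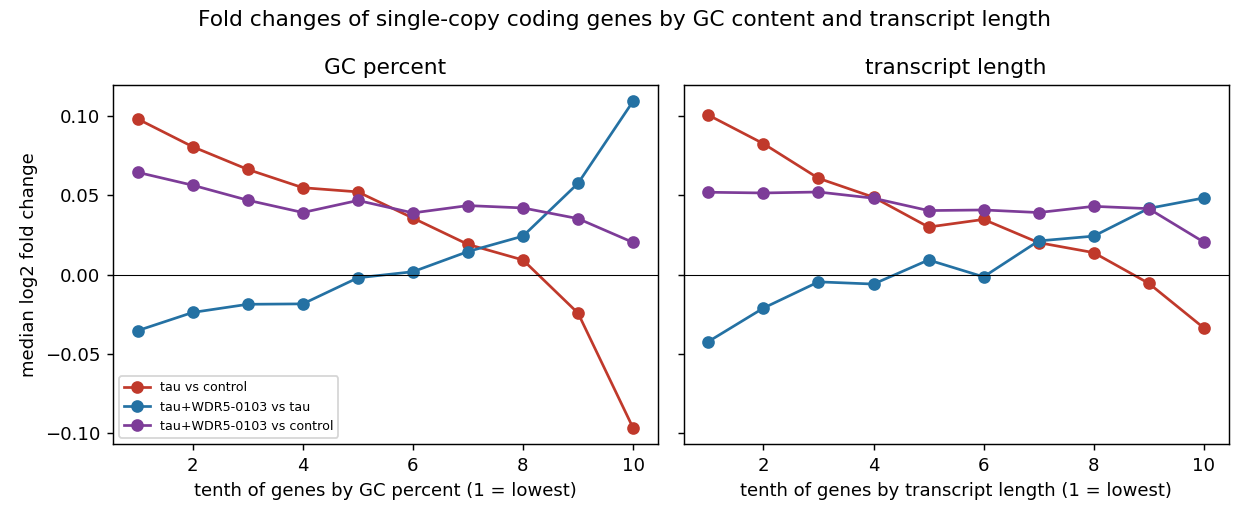
Median log2 fold change (vertical axis) of single-copy coding genes in 10 equal bins by GC content (left) and by transcript length (right), 1 line per comparison. In tau against control the medians go from 0.10 in the lowest to -0.10 in the highest bin of GC content, and the treated tau against tau line runs the other way.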

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

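Every alternative named in this part was chosen before the data were examined except the single-copy coding refit, the GC and length offsets, the sex term and the removal of the library labelled control 1 together with tau 2. For tau against control, DESeq2 called 55 genes, the exact test 49, the removal of those 2 libraries 130 and the threshold of unadjusted p with a fold of 1.2 gave 1631, where edgeR called 0 at the adjusted threshold. Leaving out 1 library gave 0 to 98. For treated tau against tau (779), the strict filter gave 465, the single-copy refit 5, and 6 with offsets, the sex term 166, the unadjusted threshold 2198, and leaving out 1 library 355 to 840. For treated tau against control (873) the strict filter gave 514, the single-copy refit 5, and 5 with offsets, the sex term 762, the unadjusted threshold 2973, and leaving out 1 library 494 to 816. Of the calls in treated tau against tau 82.0% were higher, and 61.4% with the sex term, 62.4% at the unadjusted threshold and 5 of 5 in the single-copy refit. Against control 78.7% were higher, and 64.3% with the exact test, 5 of 5 in the refit and 45.2% at the unadjusted threshold, where most were lower (1343 higher, 1630 lower). Genes moving back numbered 21 with DESeq2, 15 with the exact test, 90 without the 2 libraries, 330 at the unadjusted threshold and 0 to 14 with 1 library out. Lists called in tau against control (9) numbered 0 with an estimated correlation, 0 with fry, 5 without a filter, 5 with offsets, 4 in the single-copy fit with offsets and 5 without the 2 libraries (4 to 9 with 1 out). In treated tau against tau (5) they numbered 0, 0, 10 in the single-copy fit, 8 with offsets too and 3 without the 2 libraries (2 to 6). In treated tau against control (1) they numbered 0, 0, 2 without a filter, 2, 3 with offsets, 5 with both and 3 without the 2 libraries (1 to 7). Signs turned for Prnp in tau against control without control 2 (-0.0677, against 0.852 without the library labelled control 1) and for Sgk1 in treated tau against tau without tau 2 (0.323, against -1.14 without tau 1). They also turned for Mapt in treated tau against control without the library labelled control 1 (0.0914, against -0.264 without control 2) and Sgk1 there without treated tau 1 (-0.00388, against 0.887 without treated tau 2). For all these changes the cause was not tested; a lone library left in a group is assumed to vary like the other groups. With the replicate number as a block the gene counts were 0, 709, 796 and 0, and 7, 5 and 1 lists were called. Among lists and named genes, the calls that changed were those of the postsynaptic and ribosomal lists in tau against control (both adjusted p = 0.0566), of Rgs9 (lost) and Kcnc1 (gained) in treated tau against tau, and of Mir6236, Sntb2 and Cbln2 (lost) in treated tau against control. Deviations of same-numbered libraries correlated at 0.0101, -0.0080 and 0.0733. RLE scaling kept all 779 and all 873 calls, and no scaling moved the median of all genes by 0.1 in log2. Counts thinned to the smallest library gave 0, 707 and 751 genes.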

Other observations

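Of the tests in this part, those of GC content and length, of striatal tissue, of sex and of differing gene models were written before their result was seen. Those of shared reads, of the inhibitor and of all 3 explanations of Prnp were chosen after, as were the genes named here. Immediate early genes, which neurons switch on within minutes of activity, differed between libraries of the same group. Npas4 had 4.59 CPM in treated tau 1 and 50.6 in treated tau 2. Fos had 14.8 and 61.3, and Arc 93.2 and 409, and the list median was -0.76 and 0.81; in tau, Arc had 144 and 370.1 CPM. Egr3 differed less, with 81.1 and 91.8 CPM in treated tau against 45.3 and 62.1 in tau.

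Markers of neighbouring tissue also varied by library. The library labelled control 1 had 67.6 CPM of Omp, the olfactory marker protein gene, 27.7 of Th, which makes dopamine precursors, and 56.9 of Cdhr1, while the other 5 libraries had at most 0.634, 2.27 and 4.26 CPM. The myelin gene Mbp ranged from 537 CPM in control 2 to 2003 in tau 2. Among genes with near-copies, Rps3a1 had 25.3, 25.7 and 27.6 CPM in the first libraries of control (by its label), tau and treated tau and 1.41, 1.32 and 1.08 in the second ones, while its copy Gm13394 had 0.237, 0.274 and 2.02 against 74.8, 87.0 and 81.2. Gm7292 did not follow the number, with 0.947, 0.86 and 67.8 CPM in the first and 64.2, 64.0 and 1.16 CPM in the second libraries. Differences of at least 4-fold between the 2 libraries in all 3 groups were found in 5 of 2294 genes with near-copies and 0 of 11135 single-copy coding genes. In 4 of these 5 the library of the same number was the higher one in every group. The cause was not tested.

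The genes called between treated tau and the other libraries were mostly pseudogenes and genes with near-copies. Of the called coding genes with shared 50-mers 69.8% (67 of 96) were lower in treated tau than in tau. Reads that moved from parent genes to their copies would give that, but so would other causes of lower counts in treated tau, and the rise of 551 of the 579 called pseudogenes is the pattern itself, so a comparison with them decides nothing. Of the called genes 1.82% overlap a gene named only in the control and tau tables, against 0.829% of the uncalled (odds ratio 2.22, Fisher exact test p = 0.00834). Such overlap therefore does not account for most of the calls. Genes named only in the treated tau tables and changed models of shared symbols were not examined, so differing gene models stay open as a cause. An effect of WDR5-0103 on these transcripts and a different assignment of shared reads when the treated tables were made cannot be told apart for the called genes, because 0 libraries were counted on the other symbol list.

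Prnp in the library labelled control 1 lay at the level of the transgenic libraries. A swap with a tau or treated tau library is argued against by the lowest Prnp of those 4, 1472 CPM, which lies above the midpoint of the library labelled control 1 and control 2 (1204 CPM), so no partner is out of place. A mouse that carried the transgene (a wrong label, or an exchange with an animal outside the series) cannot be told apart from other causes. The ratio of the library labelled control 1 to control 2 lay at the 99.4 percentile of 500 genes of like expression, which restates the pattern, that of Mapt lay at the same percentile, and no table counts the human transgene. Olfactory bulb tissue stays open, since the list stood at 3.48 there and at most at -0.47 elsewhere and the Prnp level of such tissue is not known here.

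The 230 single-copy coding genes that were lower in tau and higher in treated tau include Shank1 and Bsn, and also the Y-linked genes Ddx3y, Eif2s3y, Kdm5d and Uty, which are near 0 in both female tau libraries. A GC content and length trend cannot be told apart from the rest: their median in tau against control was -0.22 (median absolute deviation 0.12) with offsets and -0.33 (0.13) without, and in treated tau against tau 0.27 (0.10) and 0.33 (0.09), but the bound set in advance was wrong, since genes picked on these folds in the same libraries keep them on average under any cause, and 98 of the 230 kept an unadjusted p under 0.05 in both comparisons. For striatal tissue the prediction was a lower level of these genes in tau 2 than in tau 1. The median difference of tau 2 minus tau 1 was 0.0342 (median absolute deviation 0.14), with 89 of the 230 lower. The sign is opposite to the prediction but lies within the spread and rests on 1 library each, so striatal tissue cannot be told apart from the rest. For sex the prediction was a higher level in the male library labelled control 1 than in the female control 2. The median difference was -0.13 (0.14), opposite in sign to the prediction, with 185 of the 230 lower in the library labelled control 1. That difference rests on 1 library each, and the label of control 1 is in doubt. Sex cannot be told apart either, because both tau libraries are female and both treated tau libraries male. An effect of tau that the inhibitor reverses is the biological explanation that the design names; it stays open and is confounded with sex and with the making of the tables.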
